A study of Mus musculus with 8 samples.

How the data were processed

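RNA was measured on Affymetrix mouse arrays with perfect-match probe sets, 1 array per sorted population and mouse, from amplified cDNA. Back skin of tumour-bearing mice was treated with thermolysin to part epidermis from dermis. Living single cells were taken by scatter, doublet exclusion and Hoechst exclusion, stained for Lrig1 and sorted by the Lgr5 reporter. The labels name no marker that excludes leukocytes and give no dose or time of vismodegib. The 8 arrays form 4 groups of 2 mice each, and both populations of a mouse share its number. All 8 columns of values were used.

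The deposited values are log2 signals that the authors made with RMA (version not stated), which corrects background, normalises by quantiles between arrays and summarises each probe set. The values were used as deposited. Over the arrays, minima lay between 3.09 and 3.17, medians between 6.13 and 6.20 and maxima between 13.3 and 13.4. The 3' minus 5' difference of control probe sets lay between −0.23 and 0.01 for Gapdh and between −0.58 and −0.34 for actin. The number of arrays limits the precision.

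Of 45141 probe sets, 104 were array controls, 28898 mapped to 1 gene symbol, 551 to several and 15588 to none. The 28898 stood for 17097 genes, of which 7180 had more than 1 probe set, and the probe set with the highest mean over the 8 arrays represented each. Genes above 4.85, the 25th percentile of all values, in at least 2 arrays were tested, which left 14403 and set aside 2694. Some named genes (Lyz2, H2-Aa, H2-Ab1, Cldn10, Lrig1, S100a8, Abi3bp, Cdca8, Prc1, Tyms, Notch3 and Lamb1) are read by probe sets of a type that can also bind related transcripts, which makes their values less certain.

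Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), in 1 model of the 4 group means with 4 residual and 3.53 prior degrees of freedom. Contrasts were the vismodegib effect in each population, the population difference in each treatment, the difference between the vismodegib effects and the population difference over both treatments. For vismodegib over both populations, the arrays of a mouse were averaged first, since the mouse is the replicate. P-values were adjusted by Benjamini and Hochberg over the 14403 genes, with a threshold of 0.05. The share of genes whose groups did not overlap was 54.8%, 51.4%, 64.6% and 43.7% for the 4 comparisons of 2 groups in the order of the Lgr5-positive drug effect, the Lgr5-negative drug effect, untreated and vismodegib populations, where chance gives 33.3%.

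A set of 36 gene lists was written for pathways, skin cell states and other cell types, and the 35 with at least 5 measured members were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a contrast. Below, a list is called or not called by this test unless another is named. The bulge, embryonic follicle and Wnt target lists hold Lgr5. The populations were sorted on it, so its difference between them was set by the sort. With the correlation estimated from the data, camera called 0 lists in any contrast. Its lowest adjusted p-values lay between 0.22 and 0.445 and the lowest unadjusted ones between 0.0135 and 0.033. The fits leave 4 residual degrees of freedom, or 2 for vismodegib over both populations. A missing call by this form of the test therefore does not show that a list did not move. An adjusted p that repeats over lists of a contrast is a value shared through the adjustment. The test fry, which asks only whether a list moves on balance in a direction, called 16, 11, 24, 2, 7, 9 and 22 lists for vismodegib in Lgr5-positive and Lgr5-negative cells, populations untreated and after vismodegib, the difference of effects, and vismodegib over both populations and populations over both treatments.

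Named genes followed a rule. It took Lgr5, Lrig1 and Ptch1, then per contrast up to 12 genes with the largest increase and 12 with the largest decrease among those past the threshold with groups that do not overlap, and up to 4 members of each list with the largest change. Where fewer than 5 passed in a direction, 5 were taken by p. The text names part of the 378 genes so taken. The groups, tests, lists, this rule and the alternatives were chosen before the data were examined, except where stated.

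The alternatives were no filter and a filter at the median (10617 genes), every probe set or the mean of probe sets, cyclic loess between arrays, an intensity trend in the prior, array weights, only the 4 arrays compared, the mouse or mouse number as a block, a random mouse block, a fold of at least 2 and leaving out each array. In deviations from group means, the arrays of the same mouse had a correlation across genes of 0.142 in untreated and 0.211 in vismodegib mice, and the correlation estimated for a random mouse block was 0.0823. The procedure was tested on simulated data with 50 changed genes per fold. It recovered 68% of 2-fold changes in the Lgr5-positive drug effect and 32% in the difference of effects, with 88% or 94% of the latter at 4-fold or 8-fold, and 52% of 2-fold changes in the Lgr5-negative drug effect. Genes left unchanged made up 3.21% of the calls for the Lgr5-positive drug effect, 5.96% for the Lgr5-negative one, 6.45% for the difference of effects, 2.60% for the untreated population difference and 9.52% (16 of 168) for that after vismodegib, so 3 of these 5 shares lay above 5%. The simulated noise was drawn independently for each gene and array, so it held no correlation between genes or between arrays of a mouse. It also held far fewer changed genes than the 1566 called for vismodegib in Lgr5-positive cells. The shares recovered and falsely called may therefore differ in the real data. Probe sets with no symbol or with several were left out of the comparisons because they name no single gene.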

Results

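Gene expression was measured on 8 arrays in cells sorted from the back skin of 4 tumour-bearing mice. The mice carried an inducible deletion of Ptch1 driven by a keratin 14 Cre, which removes the receptor that holds Smoothened in check and gives basal cell carcinoma, a skin tumour driven by the Hedgehog pathway. There were 2 untreated mice and 2 mice given vismodegib, a drug that inhibits Smoothened. From each mouse, living cells with surface Lrig1, a marker of upper follicle progenitors, were split into an Lgr5-negative and an Lgr5-positive population by a green fluorescent protein reporter of Lgr5, a receptor that marks hair follicle stem cells. Each of the 4 groups thus had n = 2 mice, and this number limits the precision of every value. The title of the series places the question in relapse after therapy, so the comparisons asked what the drug changed in each population and what set the Lgr5-positive cells apart before and after treatment. Values are log2, and each log2 fold change is given as the value ± its standard error from limma.

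The sorting marker followed the gates in every array. Lgr5 stood at 10.99 ± 0.02 (SD, n = 2) in the untreated Lgr5-positive arrays against 8.46 ± 0.09 in the Lgr5-negative arrays of the same mice. After vismodegib it stood at 9.74 ± 0.41 against 5.15 ± 0.45. Lrig1, on which both populations were selected, lay between 10.63 and 11.60 in all 8 arrays. Ptch1, which is also a target of its own pathway, stood between 10.56 and 11.91 in the untreated arrays and between 7.72 and 8.78 after vismodegib. All 8 arrays carry the deletion and its exons are not given in the sources used here, so the Ptch1 probe sets check nothing about the deletion. On the first principal component, which held 48.2% of the variance, the untreated Lgr5-positive arrays (48.9 and 45.4) lay apart from the other 6, which ranged from −31.1 to −7.13.

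**Figure D1:**
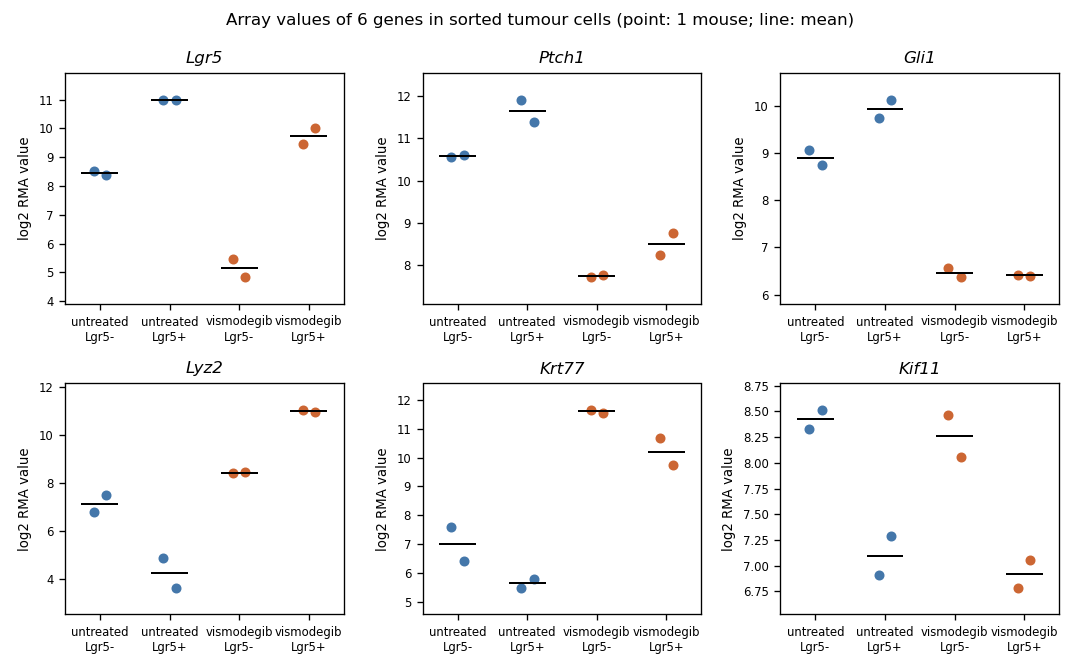
Deposited log2 values of 6 genes (vertical axes) in the 4 groups (horizontal axes), with 1 point per array, which is 1 mouse, and a line at the mean of each group. Ptch1 and Gli1 are lower after vismodegib in both populations, Lyz2 is highest in the vismodegib Lgr5-positive arrays, and Lgr5 is lowest in the vismodegib Lgr5-negative arrays, at 5.46 and 4.83.

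In Lgr5-positive cells, Hedgehog targets and hair follicle progenitor genes fell after vismodegib, while genes of upper follicle and interfollicular epidermis and markers of macrophages rose. Each of these 5 lists had an adjusted p = 0.221 with an estimated correlation. Gli1, the transcription factor that carries the Hedgehog signal, fell 11.5-fold (log2 fold change −3.52 ± 0.17, adjusted p = 0.000101), and the pathway inhibitors Hhip (−3.94 ± 0.36) and Ptch1 (−3.13 ± 0.22, or −2.26 by its other probe set), both induced by the signal, fell with it. Lgr5 itself was lower by 2.38-fold (−1.25 ± 0.25). Krt77, a keratin of suprabasal and sweat duct keratinocytes, rose 23.5-fold (4.55 ± 0.41). At an adjusted p under 0.05, 917 of the 14403 tested genes were higher and 649 lower after vismodegib, and 739 of these 1566 genes changed at least 2-fold.

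The Hedgehog list had 7 lower and 0 higher members of 17 measured (1 and 10 adjusted over the list alone), among them Mycn (−1.44 ± 0.14), with a median of −0.63. Here and below, such a pair of counts gives the members higher and lower. Of 18 embryonic hair follicle progenitor genes, 9 fell and 1 rose (1 and 10 adjusted over the list alone). The follicle stem cell regulator Lhx2 (−3.08 ± 0.18), the transcription factor Tbx1 (−2.53 ± 0.29) and the adhesion molecule Ncam1 (−2.38 ± 0.53) fell, and the matrix protein tenascin C (Tnc, 2.41 ± 0.17) was the riser. Bulge stem cell and outer root sheath genes had 9 of 21 lower and 1 higher (1 and 10 adjusted over the list alone), with the secreted Wnt inhibitors Wif1 (−2.26 ± 0.20) and Dkk3 (−1.67 ± 0.22) among them. The water channel Aqp3 (3.75 ± 0.34) rose. Wnt targets moved both ways, and the list, with 2 higher and 5 lower of 22 (4 and 6 adjusted over the list alone) and a median of −0.14, was not called. Its members Tnfrsf19 (2.63 ± 0.15) and Apcdd1 (2.14 ± 0.31) rose and Lef1 (−1.76 ± 0.19) fell. Cell cycle inhibitor and quiescence genes had 0 higher and 4 lower of 19 (1 and 7 adjusted over the list alone), led by Cdkn2b, which encodes p15 (−2.75 ± 0.26). The 4 lists of Hedgehog, embryonic follicle, bulge and quiescence genes were called with the preset correlation, and each had an adjusted p = 0.221 with an estimated correlation. Some share members, such as Lhx2 and Lgr5 (embryonic follicle and bulge) and Foxc1 (bulge and quiescence), so their results are not independent.

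Part of the immediate early genes and of the EGFR and ERK list fell as well in Lgr5-positive cells. Immediate early genes, which answer growth factors and stress within minutes, had 10 of 21 lower and 0 higher (1 and 12 adjusted over the list alone), such as Egr3 (−1.13 ± 0.14) and Junb (−1.01 ± 0.19). In the EGFR and ERK list, 6 of 23 were lower and 1 higher (2 and 9 adjusted over the list alone). The feedback inhibitor Spry4 (−3.31 ± 0.15) and the ETS factor Etv4 (−2.28 ± 0.19), both induced by ERK, led the decrease. Cholesterol and fatty acid synthesis had 5 of 21 lower and 0 higher (0 and 9 adjusted over the list alone), including lanosterol synthase (Lss, −1.14 ± 0.28) and the fatty acid elongase Elovl6 (−1.63 ± 0.42). Each of these 3 lists had an adjusted p = 0.221 with an estimated correlation. Outside the lists, the amino acid transporter Slc7a2 (−4.23 ± 0.28), the transcription factor Sox13 (−3.84 ± 0.22) and the claudin Cldn10 (−3.66 ± 0.17) showed some of the largest decreases.

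Among genes that rose, interfollicular epidermis differentiation had 9 higher and 0 lower of 26 (15 and 0 adjusted over the list alone) at a median of 0.94, with the cornified envelope precursor Sprr1a (2.30 ± 0.43) beside Krt77. Infundibulum and upper follicle genes had 7 higher and 1 lower of 12 (8 and 1 adjusted over the list alone), including the protease inhibitor Cst6 (3.30 ± 0.35) and the antimicrobial peptide Defb6 (2.14 ± 0.30). Ribosome biogenesis genes had 8 of 23 higher and 0 lower (9 and 0 adjusted over the list alone), with ornithine decarboxylase (Odc1) 2.3-fold higher. These 3 lists had an adjusted p = 0.221 with an estimated correlation.

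Markers of Langerhans cells, dendritic cells and macrophages moved with this comparison. Of 22 measured, 17 rose and 0 fell (18 and 1 adjusted over the list alone), with a median of 2.29 and an adjusted p = 4.65e-15 with the preset correlation, or 0.221 as adjusted p with an estimated correlation. Lysozyme (Lyz2, 6.73 ± 0.38), cathepsin S (Ctss, 5.62 ± 0.58), the myeloid signalling adaptor Tyrobp (3.98 ± 0.29) and the complement component C1qb (3.96 ± 0.17) were among them, and the platelet and macrophage chemokine Pf4 rose too (3.91 ± 0.32). MHC genes had 5 of 13 higher and 0 lower (6 and 0 adjusted over the list alone), and the risers included the class II genes H2-Aa (4.35 ± 0.73), H2-Ab1 (2.13 ± 0.13) and their chaperone Cd74 (3.34 ± 0.33), which the macrophage list also holds (adjusted p = 0.221 with an estimated correlation). Interferon response genes had 1 of 16 higher and 1 lower (3 and 1 adjusted over the list alone), with a median of 0.44 and 13 above 0. That list had an adjusted p = 0.0485 with the preset correlation, which did not pass without either untreated Lgr5-positive array or vismodegib Lgr5-positive array 2, and an adjusted p = 0.519 with an estimated correlation. T cell markers had 1 of 14 higher (1 and 0 adjusted over the list alone) at a median of 0.11, dermal fibroblast markers had 1 of 12 lower (0 and 2 adjusted over the list alone) at a median of −0.29, and neither list was called by camera with the preset correlation. Endothelial and pericyte markers had 0 higher and 2 lower of 15 (0 and 2 adjusted over the list alone) at a median of −0.21, called lower with the preset correlation (adjusted p = 0.0487) and at an adjusted p = 0.221 with an estimated correlation. That call passed without untreated Lgr5-positive array 2 but not without any other single array, nor after cyclic loess (adjusted p = 0.118) or with no filter (0.0695). Lrig1 differed by −0.15 ± 0.17 and did not pass.

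Without vismodegib Lgr5-positive array 1 the count was 543, without array 2 of that group 768 and without untreated Lgr5-positive array 2 it was 1037. In the first of these fits Lgr5, Ncam1, Junb, Elovl6, Lss, Sprr1a and H2-Aa did not pass, and leaving out any of the other 7 arrays ended between 1 and 6 calls of named genes. As the mean of their probe sets Tnc (1.28), Spry4 (−1.74) and H2-Aa (2.42) passed with smaller changes.

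In Lgr5-negative cells, Lgr5, the Hedgehog targets Gli1 and Ptch1, the alarmin gene S100a9 and epiregulin fell after vismodegib, and Krt77 and the chemokine gene Cxcl9 rose. Lgr5 fell 9.94-fold (−3.31 ± 0.25), from a level that was already 5.77-fold under that of Lgr5-positive cells, while its other probe set gave −1.89, and 1 of the treated arrays lay at 4.83, under the 4.85 set for dim genes. The Wnt inhibitor Wif1 fell 11.5-fold (−3.53 ± 0.20). Gli1 (−2.44 ± 0.17), Ptch1 (−2.84 ± 0.22) and Hhip (−2.02 ± 0.36) fell, although the other Ptch1 probe set gave −1.23 and Hhip did not pass as the mean of its probe sets (−1.12, adjusted p = 0.116). Krt77 rose 24.1-fold (4.59 ± 0.41), and the basal and bulge keratin Krt15 rose as well (2.15 ± 0.17). In all, 181 genes were higher and 297 lower at an adjusted p under 0.05, and 262 of the 478 changed at least 2-fold.

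Wound and stress keratins and alarmins had 8 of 17 lower and 0 higher (1 and 13 adjusted over the list alone), the largest median shift of any list in these cells (−1.93). The list had an adjusted p = 0.252 with an estimated correlation. It shares S100a8 and S100a9 with the mast cell and neutrophil list of 9 members. That list's mean, these genes included, went from 7.15 and 7.35 to 6.81 and 6.57. The falls of S100a8 and S100a9 alone more than account for this, so it does not show that the list's other members fell. The calprotectin genes S100a8 (−3.42 ± 0.64) and S100a9 (−3.08 ± 0.51), the EGFR ligand epiregulin (Ereg, −2.05 ± 0.11) and the envelope protein gene Sprr1b (−2.33 ± 0.37) fell, and Krt6b stood at −2.50 ± 0.65 without passing. With the mouse number as a block S100a8 had an adjusted p = 0.0583 and Krt6b 0.0352. Sprr2d, of the same envelope family, fell too (−3.96 ± 0.41), and so did the transglutaminase Tgm3 (−2.39 ± 0.15). Cell cycle and mitosis genes had 4 of 31 lower (0 and 14 adjusted over the list alone), such as Cdca3 (−1.23 ± 0.17), and all 31 values lay below 0 (median −0.59, adjusted p = 0.399 with an estimated correlation). DNA replication genes had 3 of 27 lower (0 and 11 adjusted over the list alone), among them Gins1 (−1.26 ± 0.21) and the ribonucleotide reductase subunit Rrm2 (−1.07 ± 0.19, adjusted p = 0.0539 with that block), with an adjusted p = 0.274 with an estimated correlation.

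The Hedgehog list had 5 of 17 lower and 0 higher (1 and 7 adjusted over the list alone), with a median of −0.31 (adjusted p = 0.36 with an estimated correlation). Embryonic follicle genes had 4 of 18 lower (0 and 7 adjusted over the list alone), including Ncam1 (−3.04 ± 0.53) and Lhx2 (−1.98 ± 0.18), with an adjusted p = 0.341 with an estimated correlation. Spry4 (−1.28 ± 0.15) fell within the EGFR and ERK list, which had 0 higher and 4 lower of 23 (3 and 7 adjusted over the list alone) and an adjusted p = 0.427 with an estimated correlation. Slc7a2 (−3.01 ± 0.28) and the thyroid hormone activating deiodinase Dio2 (−2.91 ± 0.21) were lower outside the lists. Cholesterol and fatty acid synthesis was called with a median of −0.51, though 0 of its 21 members passed over all genes (0 and 3 adjusted over the list alone). Its adjusted p was 0.252 with an estimated correlation.

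Of the genes that rose in Lgr5-negative cells, the matrix protein Thbs2 (3.76 ± 0.53) and the G protein regulator Rgs4 (3.49 ± 0.42) had large changes. Interferon response genes had 2 of 16 higher and 0 lower (7 and 0 adjusted over the list alone), including the chemokine Cxcl9 (2.74 ± 0.31), with a median of 0.80 and an adjusted p = 0.274 with an estimated correlation. Of 13 MHC genes 3 were higher (5 and 0 adjusted over the list alone), among them Nlrc5, the activator of class I genes (1.28 ± 0.20), with an adjusted p = 0.252 with an estimated correlation. The macrophage list had 4 of 22 higher and 0 lower (9 and 0 adjusted over the list alone) at a median of 0.72, with C1qb at 1.99 ± 0.17 and C1qa at 1.72 ± 0.19, while Lyz2 at 1.29 ± 0.38 did not pass. Its adjusted p was 0.341 with an estimated correlation. Infundibulum genes had 3 of 12 higher (3 and 0 adjusted over the list alone), including Cst6 (2.35 ± 0.35), with an adjusted p = 0.427 with an estimated correlation. Lrig1 at 0.43 ± 0.17 did not pass.

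Leaving out array 1 or 2 of the untreated Lgr5-negative group gave 137 or 65 genes, vismodegib Lgr5-negative array 2 gave 257 and either vismodegib Lgr5-positive array 272. In the fit with 65 genes the named genes that did not pass were Hhip, S100a8, S100a9, Sprr1b, Sprr2d, Cdca3, Gins1, Rrm2, Ncam1, Spry4, Thbs2, Rgs4, Cxcl9, Nlrc5 and Cst6, and each other array but the untreated Lgr5-positive ones ended between 7 and 14 of the calls. As the mean of their probe sets Ncam1 (−1.86) and Spry4 (−0.49) passed with smaller changes.

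The Lgr5-positive and Lgr5-negative changes were also set against each other. Across all genes the 2 sets of log2 fold changes had r = 0.441 (Spearman's rho 0.261), with genes not being independent replicates. Of the genes past the threshold in both populations, 113 were higher and 108 lower in both, and 20 went opposite ways. The comparisons use different arrays of the same 4 mice, so what a mouse's arrays share enters both, and no test of the overlap was made.

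Vismodegib changed 202 genes to a different extent in the 2 populations, most of them upward in Lgr5-positive relative to Lgr5-negative cells (143 against 59). Large differences were in myeloid genes. Lyz2 gained 5.44 ± 0.53 more on the log2 scale in Lgr5-positive cells, Ctss 4.91 ± 0.82, Pf4 4.26 ± 0.46 and Tyrobp 3.28 ± 0.40, and the neutrophil chemokine Cxcl2 5.03 ± 0.51. The keratinocyte stress and envelope genes Krt16 (2.42 ± 0.24), Sprr2d (3.55 ± 0.59), Tgm3 (2.79 ± 0.21) and Ereg (1.97 ± 0.16) also had positive differences. For Sprr2d (−3.96), Tgm3 (−2.39) and Ereg (−2.05) these came with a fall in Lgr5-negative cells. Tnc (2.99 ± 0.24) and Aqp3 (3.09 ± 0.49) were among the largest of the other risers.

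On the side where Lgr5-positive cells lost more were Spry4 (−2.03 ± 0.22), Cldn10 (−2.47 ± 0.24), Sox13 (−2.14 ± 0.31), Tbx1 (−2.39 ± 0.40), the immediate early gene Jun (−1.16 ± 0.18) and the follicle transcription factor Foxc1 (−1.49 ± 0.20). Krt15, which rose in Lgr5-negative cells, differed by −1.73 ± 0.24. Lgr5 fell less in Lgr5-positive cells, by a difference of 2.06 ± 0.35. For the Hedgehog genes Ptch1 (−0.30 ± 0.31) and Gli1 (−1.08 ± 0.24), the difference between populations did not pass. Odc1 (1.21 ± 0.19) and the replication gene Tyms (1.21 ± 0.20) differed in favour of Lgr5-positive cells. As the mean of their probe sets Lgr5 (1.44, adjusted p = 0.053) and Tyms (0.26, adjusted p = 0.339) did not pass, nor did Tyms after cyclic loess (adjusted p = 0.0521), while Spry4 (−1.25) and Tnc (1.74) passed with smaller differences.

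By lists, macrophage markers had 6 of 22 with a more positive effect in Lgr5-positive cells and 0 with a more negative one (15 and 1 adjusted over the list alone), at a median of 1.33 and an adjusted p = 0.396 with an estimated correlation. Wound and stress genes had 4 of 17 (9 and 0 adjusted over the list alone) at a median of 1.97, immediate early genes had 1 of 21 in the other direction (0 and 12 adjusted over the list alone) at a median of −0.61, each with an adjusted p = 0.372 with an estimated correlation. The wound list's mean fell in Lgr5-negative arrays, from 8.83 and 9.38 to 7.65 and 7.35. In Lgr5-positive arrays it was 6.95 and 7.43 before and 7.31 and 7.31 after vismodegib. Cell cycle genes had a median of 0.44 with 0 of 31 past the threshold (5 and 0 adjusted over the list alone) and an adjusted p = 0.487 with an estimated correlation. DNA replication (0.53), interfollicular differentiation (0.93), ribosome biogenesis (0.39) and oxidative phosphorylation (0.45) were called upward, each with an adjusted p = 0.424 with an estimated correlation.

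Without vismodegib Lgr5-positive array 1 or 2 the count was 2 or 79, without untreated Lgr5-negative array 1 or 2 it was 66 or 8, and without vismodegib Lgr5-negative array 2 it was 109. All 21 genes named as past the threshold lost their call in the first of these fits, and each other array ended between 4 and 19 of the calls. With the mouse as a block, Lgr5 (adjusted p = 0.0538) and Odc1 (adjusted p = 0.0536) no longer passed.

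**Figure D2:**
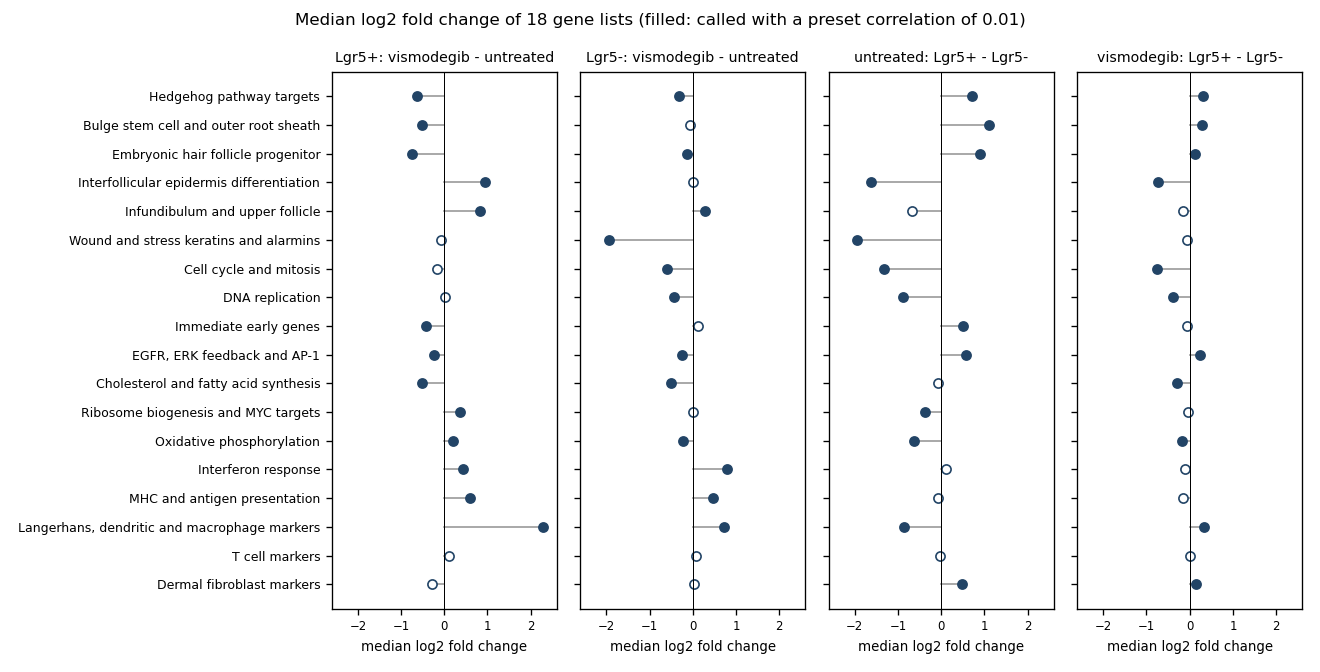
Median log2 fold change (horizontal axes) of 18 gene lists (vertical axis) in the 4 comparisons of 2 groups, with filled points for lists called at an adjusted p under 0.05 with the preset correlation. The macrophage list has the largest shift in Lgr5-positive cells, at 2.29, and the wound list the largest in Lgr5-negative cells, at −1.93, and no list is called with an estimated correlation.

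In untreated mice, Lgr5-positive cells had higher follicle stem cell and Hedgehog genes and lower proliferation, differentiation and wound genes than Lgr5-negative cells. The sort as described used no marker of tumour cells, so normal cells may be part of either population. The lists of these genes had an adjusted p = 0.22 with an estimated correlation. Lgr5 was 5.77-fold higher (2.53 ± 0.25), Lhx2 4.73-fold (2.24 ± 0.18) and Hhip 3.85-fold (1.95 ± 0.36). The lipid transporter Abca12, needed for the skin barrier, was 19.3-fold lower (−4.27 ± 0.17) and the stress serpin Serpinb2 25.4-fold lower (−4.67 ± 0.46). Of 14403 genes, 895 were higher and 1571 lower in Lgr5-positive cells, and 960 of the 2466 differed at least 2-fold.

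Cell cycle and mitosis genes had 23 of 31 lower and 0 higher (0 and 26 adjusted over the list alone), such as Cdca8 (−2.05 ± 0.35), Melk (−1.85 ± 0.20) and the spindle midzone protein Prc1 (−1.66 ± 0.18). The median was −1.32. DNA replication genes had 17 of 27 lower and 0 higher (0 and 19 adjusted over the list alone), including the helicase subunit Mcm5 (−1.48 ± 0.14) and thymidylate synthase (Tyms, −1.62 ± 0.14). The cell cycle inhibitor and quiescence list had 6 of 19 higher and 0 lower (6 and 1 adjusted over the list alone), among them Cdkn2b (1.75 ± 0.26), Klf9 (1.55 ± 0.14) and Foxc1 (1.38 ± 0.14). These 3 lists had an adjusted p = 0.22 with an estimated correlation.

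Bulge stem cell and outer root sheath genes had 14 of 21 higher and 1 lower (16 and 1 adjusted over the list alone) at a median of 1.10, including Krt15 (1.65 ± 0.17). Embryonic follicle genes had 10 of 18 higher and 1 lower (11 and 1 adjusted over the list alone), with Tbx1 at 2.10 ± 0.29 and Tnc lower at −2.52 ± 0.17. The bulge and embryonic follicle lists both count Lgr5, the gene of the sort. Of 17 Hedgehog genes 9 were higher and 0 lower (10 and 0 adjusted over the list alone), among them the coreceptor Boc (1.23 ± 0.22), Mycn (1.17 ± 0.14) and Ptch1 (1.07 ± 0.22). Immediate early genes had 12 of 21 higher (18 and 0 adjusted over the list alone), such as Nr4a1 (1.25 ± 0.20) and Junb (0.94 ± 0.19), and the EGFR and ERK list 11 of 23 higher and 2 lower (14 and 3 adjusted over the list alone), with Spry4 at 2.33 ± 0.15 and Etv4 at 1.37 ± 0.19. All 5 lists had an adjusted p = 0.22 with an estimated correlation. The secreted protein Fstl1 (2.62 ± 0.29), the cartilage collagen Col2a1 (2.48 ± 0.39) and the matrix protein Abi3bp (2.54 ± 0.35) led the higher genes outside the lists. Dermal fibroblast markers moved with them and were called higher with the preset correlation, with 3 of 12 higher and 1 lower (7 and 1 adjusted over the list alone), 11 above 0 and a median of 0.48. Col6a1 (2.09 ± 0.20), Col1a1 (0.88 ± 0.17) and Sparc (0.97 ± 0.24) were the higher members, and the list had an adjusted p = 0.22 with an estimated correlation.

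Interfollicular differentiation had 16 of 26 lower and 0 higher (0 and 20 adjusted over the list alone) at a median of −1.63, with Casp14 (−3.78 ± 0.58) and Tgm3 (−3.19 ± 0.15) among them. Wound and stress genes had 13 of 17 lower and 0 higher (0 and 14 adjusted over the list alone) at a median of −1.96, including Krt6b (−3.94 ± 0.65), Sprr1b (−3.41 ± 0.37) and the cytokine Il1f9 (−3.73 ± 0.54). Both lists had an adjusted p = 0.22 with an estimated correlation. Glycolysis and hypoxia genes had 12 of 20 lower and 2 higher (2 and 15 adjusted over the list alone), with the oxygen sensor Egln3 at −3.17 ± 0.61, and oxidative phosphorylation 9 of 23 lower and 0 higher (0 and 22 adjusted over the list alone), with the complex I subunit Ndufb5 at −0.87 ± 0.16. For both, adjusted p = 0.292 with an estimated correlation. Macrophage markers moved with this comparison too, with 8 of 22 lower in Lgr5-positive cells and 0 higher (0 and 11 adjusted over the list alone), such as Ctss (−4.03 ± 0.58), H2-Aa (−3.91 ± 0.73) and Lyz2 (−2.89 ± 0.38), at an adjusted p = 0.292 with an estimated correlation. Lrig1 was 1.73-fold higher in Lgr5-positive cells (0.79 ± 0.17).

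Leaving out untreated Lgr5-negative array 1 or 2 gave 1034 or 582 genes, and the latter fit ended the calls of Lrig1, Ptch1, Hhip, Boc, Nr4a1, Junb, Cdca8, Casp14, Krt6b, Il1f9, Ndufb5, Egln3, H2-Aa, Col1a1 and Sparc, while array 1 of that group and the untreated Lgr5-positive arrays ended between 2 and 9 calls of named genes. As the mean of their probe sets Boc (0.64), Tnc (−1.55), Spry4 (1.31), Mcm5 (−0.83), Tyms (−0.38) and H2-Aa (−2.36) passed with smaller differences.

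After vismodegib, the populations differed in few single genes. Lgr5 was 24.1-fold higher (4.59 ± 0.25), or 3.22 on the log2 scale by its other probe set, and 1 of the Lgr5-negative arrays lay under the 4.85 set for dim genes. The matrix proteins Abi3bp and Sparc were 15.7-fold (3.97 ± 0.35) and 7.04-fold (2.82 ± 0.24) higher, and Krt75, a keratin of the companion layer of the hair follicle, was 7.87-fold higher (2.98 ± 0.25). Sparc belongs to both the fibroblast and the matrix list. Dermal fibroblast markers had 1 of 12 higher and 0 lower (2 and 0 adjusted over the list alone) at a median of 0.15 with 10 above 0, and the matrix list 1 of 16 higher and 0 lower (4 and 0 adjusted over the list alone) at a median of 0.35 with 13 above 0. Both were called with the preset correlation and had an adjusted p = 0.315 with an estimated correlation, and 0.0447 and 0.0387 as fry's adjusted p for 1 direction. The decoy receptor for interleukin 1, Il1r2, was 4.19-fold lower (−2.07 ± 0.13). At an adjusted p under 0.05, 49 genes were higher and 19 lower, and with the mouse as a block the count was 105 in place of 68.

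Cell cycle and mitosis genes were all lower in Lgr5-positive cells by value, 31 of 31, with a median of −0.75, although 1 passed over all genes (0 and 19 adjusted over the list alone), the mitotic kinesin Kif11 (−1.34 ± 0.20). The list had an adjusted p = 0.315 with an estimated correlation. Outside it, separase (Espl1, −1.33 ± 0.19) and the centriole gene Stil (−1.23 ± 0.18) were lower. DNA replication (median −0.40), interfollicular differentiation (−0.73) and cholesterol synthesis (−0.30) were called lower with 0 members past the threshold, each with an adjusted p = 0.315 with an estimated correlation. Bulge genes had 2 of 21 higher (7 and 0 adjusted over the list alone), Lgr5 and Wif1 (2.28 ± 0.20), with a median of 0.29 and an adjusted p = 0.315 with an estimated correlation. Lgr5 was the gene of the sort, so its place among them was set by the gate. Lhx2 at 1.14 ± 0.18 had an adjusted p = 0.0591 (0.0453 after cyclic loess), and Ptch1 (0.77 ± 0.22), Lrig1 (0.21 ± 0.17) and Krt77 (−1.40 ± 0.41) did not pass. The Hedgehog list was called higher with a median of 0.30 and 0 of 17 members past the threshold (4 and 0 adjusted over the list alone), at an adjusted p = 0.436 with an estimated correlation.

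Macrophage markers had 3 of 22 higher in Lgr5-positive cells and 0 lower (6 and 1 adjusted over the list alone), namely Lyz2 (2.56 ± 0.38), Mrc1 (2.37 ± 0.34) and Cd68 (2.00 ± 0.25), with 14 above 0 and 8 below and an adjusted p = 0.607 with an estimated correlation. A further 32 myeloid genes had a median difference of 0.08. The chemokines Pf4 (3.86 ± 0.32), Ccl6 (3.23 ± 0.21) and Cxcl2 (3.08 ± 0.36) and the latent TGF-beta binding protein Ltbp2 (1.93 ± 0.21) were higher too. With the mouse as a block, Lyz2 had an adjusted p = 0.0543.

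Fitted on the 4 arrays of these 2 groups alone 11 genes passed, and 36 passed with no filter on dim genes. The count was 18 or 107 without vismodegib Lgr5-negative array 1 or 2, 30 or 29 without vismodegib Lgr5-positive array 1 or 2 and 20 without either untreated Lgr5-negative array, and the fit with 18 ended the calls of Lyz2, Mrc1, Cd68, Cxcl2, Ltbp2, Kif11, Espl1 and Stil, while each other array ended between 2 and 7 calls of named genes.

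The difference between populations spread less over the genes in both vismodegib mice than in both untreated mice. The standard deviation over genes of the Lgr5-positive minus Lgr5-negative difference was 0.579 and 0.601 in the untreated mice and 0.412 and 0.330 in the vismodegib mice. The 355 genes at least 2-fold higher in the Lgr5-positive cells of untreated mouse 1 had a median difference of 1.26 in untreated mouse 2, against 0.35 and 0.51 in the vismodegib mice. For the 711 genes at least 2-fold lower there, the medians were −1.22 against −0.51 and −0.29. Chosen in vismodegib mouse 1, the 162 genes at least 2-fold higher went the other way, with a median of 0.85 in vismodegib mouse 2 against 0.40 and 0.28 in the untreated mice, and the 224 lower genes had −0.414 against −0.997 and −0.930. Chosen in vismodegib mouse 2, the 165 higher genes had 0.82 in vismodegib mouse 1 against 0.96 and 0.91 in the untreated mice, and the 64 lower genes −0.84 against −1.51 and −1.27. Of the genes past the threshold in both treatments, 24 were higher and 13 lower in Lgr5-positive cells both times, where independent lists would share 3.04 and 2.07, and 3 went opposite ways. Across all genes the differences had r = 0.439 (rho 0.364), and genes are not independent replicates.

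Averaged over both populations of each mouse, vismodegib raised 512 genes and lowered 462. Gli1 (−2.98 ± 0.09), Ptch1 (−2.98 ± 0.14), Hhip (−2.98 ± 0.27, or −1.94 as the mean of its probe sets) and Lgr5 (−2.28 ± 0.09) fell, as did Wif1 (−2.89 ± 0.16), Slc7a2 (−3.62 ± 0.23) and the pseudokinase Trib2 (−3.03 ± 0.09). Krt77 (4.57 ± 0.22), Cst6 (2.83 ± 0.24) and Lyz2 (4.01 ± 0.12) rose. The Hedgehog list had 7 of 17 lower and 0 higher (1 and 9 adjusted over the list alone), at an adjusted p = 0.462 with an estimated correlation. Cholesterol synthesis had 6 of 21 lower (0 and 13 adjusted over the list alone) and macrophage markers 15 of 22 higher (18 and 1 adjusted over the list alone), each with an adjusted p = 0.445 with an estimated correlation. With the mouse as a random block in the 4-group model, 1568 genes passed in place of 974. Without untreated mouse 1 or 2 the count was 415 or 330, and 0 of the 10 genes named here lost its call.

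Averaged over both treatments, 783 genes were higher and 1206 lower in Lgr5-positive cells. Lgr5 (3.56 ± 0.17), Abi3bp (3.25 ± 0.24), Krt75 (2.40 ± 0.17), Sparc (1.89 ± 0.17), Lhx2 (1.69 ± 0.13) and Klf9 (1.05 ± 0.10) were higher. Serpinb2 (−3.23 ± 0.33), Krt6b (−2.85 ± 0.46), Il1r2 (−2.24 ± 0.09), Kif11 (−1.33 ± 0.14) and cyclin A2 (Ccna2, −1.31 ± 0.18) were lower. Cell cycle and mitosis genes had 23 of 31 lower and 0 higher (0 and 29 adjusted over the list alone) at a median of −1.12, and bulge genes 14 of 21 higher and 1 lower (17 and 1 adjusted over the list alone) at a median of 0.70. Both lists had an adjusted p = 0.243 with an estimated correlation. The bulge list counts Lgr5, the gene of the sort. The count was 1005 or 742 without untreated Lgr5-negative array 1 or 2, 1113 or 865 without vismodegib Lgr5-positive array 1 or 2, and 1221 without vismodegib Lgr5-negative array 1. Leaving out any 1 array ended 0 calls of the 11 genes named here.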

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

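Of the tests given here, those on other cell types, the interferon list, the spread between mice, the Lgr5 gate, cell preparation and ERK signalling were chosen after the result was seen. The effect of vismodegib differed between the populations in 202 genes by limma's test of the difference itself. Without vismodegib Lgr5-positive array 1 or 2 the count was 2 or 79, without untreated Lgr5-negative array 1 or 2 it was 66 or 8, and without vismodegib Lgr5-negative array 2 it was 109.

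Among genes named by the rule, the change was larger on the positive side in Lgr5-positive cells for Lyz2 (5.44), Cxcl2 (5.03), Ctss (4.91), Pf4 (4.26), Sprr2d (3.55), Tyrobp (3.28), Aqp3 (3.09), Tnc (2.99), Tgm3 (2.79), Vim (2.53), Krt16 (2.42), Lgr5 (2.06), C1qb (1.97), Ereg (1.97), Tnfrsf19 (1.42), H2-Ab1 (1.40), Tyms (1.21) and Odc1 (1.21). It was on the negative side for Cldn10 (−2.47), Tbx1 (−2.39), Sox13 (−2.14), Spry4 (−2.03), Krt15 (−1.73), Foxc1 (−1.49), Lamb1 (−1.46) and Jun (−1.16). These are log2 differences between the effects. A positive value can also come with a fall in Lgr5-negative cells, as for Lgr5 (−3.31), Sprr2d (−3.96), Tgm3 (−2.39) and Ereg (−2.05).

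The medians of that difference were positive in the lists of wound and stress genes (1.97), macrophage markers (1.33), interfollicular differentiation (0.93), glycolysis and hypoxia (0.55), DNA replication (0.53), oxidative phosphorylation (0.45), cell cycle (0.44) and ribosome biogenesis (0.39). They were negative for immediate early genes (−0.61), cell cycle inhibitors (−0.41), bulge genes (−0.38), embryonic follicle genes (−0.31), Hedgehog targets (−0.30), interferon response (−0.28) and endothelial markers (−0.22). These 15 lists were called with the preset correlation, and the lowest adjusted p was 0.372 with an estimated correlation. A positive median can also come with a fall in Lgr5-negative cells, as for wound and stress, DNA replication and cell cycle genes.

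Macrophage markers rose in the Lgr5-positive cells after vismodegib. The lists of 6 other cell types had a highest median of 0.11. This goes against a lower share of keratinocytes that raised the markers of all other types alike. It cannot speak to a share taken by myeloid cells alone, which would leave these lists unmoved. The endothelial, melanocyte and muscle lists also had means under the array medians in every array, so they could hide a small rise. An interferon response of the keratinocytes is argued against as the reason for a larger rise than in Lgr5-negative cells. The interferon list's median difference was −0.28, with 14 of 16 genes below 0. Such a response stays open for the rise itself. The list's median in Lgr5-positive cells was 0.44, with 13 above 0 and a camera adjusted p = 0.519 with an estimated correlation. Myeloid cells among the sorted cells may be a source, and the 32 measured genes of 35 further myeloid genes, of which 0 are in the other lists, had a median of 0.66 (quartiles 0.18 and 1.53) with 14 higher and 0 lower. This lies between the bounds of 0.5 and 1 set for the test. The test thus cannot tell myeloid cells apart from myeloid genes raised in the keratinocytes. The 14 higher genes included Cd53 (2.93, to 8.48), Lcp1 (2.78), Ms4a7 (2.31), Clec7a (2.29), Fcgr2b (2.00), Coro1a (1.63), Cd52 (1.49, to 8.76) and Cd14 (1.45). The rest did not pass. Arhgdib and Sirpa stood at 10.17 and 9.03 before the drug, too high to show a small share. Ccl4 (5.66 to 5.65) and Clec4a2 (6.24 to 6.26) lay near or under the array medians in every group. Such genes may not show a small share either, and they enter the median. The Lrig1 and Lgr5 gates select against cells without these markers, and the effect of the drug on the tumour itself stays open and untested.

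The populations differed less after vismodegib. A larger spread between the vismodegib mice as the whole cause would leave or raise the standard deviation of the population difference within a mouse, but this was 0.412 and 0.330 in the vismodegib mice and 0.579 and 0.601 in the untreated mice. Of the 4 sets of genes at least 2-fold apart in a vismodegib mouse, 3 had larger medians in both untreated mice than in the other vismodegib mouse, while the set higher in vismodegib mouse 1 had smaller medians there, 0.40 and 0.28 against 0.85. Lgr5 itself differed by 3.98 and 5.20 in the vismodegib mice against a mean of 2.53 in the untreated mice. The gain was 2.06 (adjusted p = 0.0538 in limma with the mouse as a block, 0.053 as the mean of its probe sets). By its other probe set the difference was 3.22 against 2.41. The gain came with a fall of Lgr5 in Lgr5-negative cells (−3.31), and Lgr5 fell in Lgr5-positive cells too (−1.25). It therefore cannot tell whether the Lgr5-positive gate held, and a poorer gate stays open. The treatment itself stays open and was not tested apart from the mice that received it.

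With an estimated correlation camera called no list for vismodegib in Lgr5-positive cells (lowest adjusted p = 0.221). With that limit, immediate early genes tended to fall there. A difference in cell preparation between the untreated and treated mice would lower them in both populations, but their median in Lgr5-negative cells was 0.13, with 15 of 21 above 0. Lower ERK signalling in Lgr5-positive cells might contribute, and the 22 genes of the EGFR and ERK list that are not immediate early genes had a median difference of −0.30, with 15 below 0 and a camera adjusted p of 0.0964, so the test leaves it open. That fit had no mouse block. With the preset correlation, the whole list had a camera adjusted p = 0.0724 without the block and 0.0463 with it. The order and length of the sorts are not given in the sources used here and were not tested.

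The population difference over both treatments was set against other splits of the 8 arrays into 4 and 4. In a limma model with the split alone, which leaves treatment and mouse in the residual spread, 2 of 35 splits gave as many genes, the real one with 29 and the split by treatment with 329. A share of 2 in 35 does not exclude chance by the bound of 0.05, but the larger count is that of the treatment, a structure of the samples, and none of the remaining splits gave as many as 29. Of the splits that part the arrays of each mouse there are 8, too few for a share under 0.05, and the real one gave 1989 genes against 202 for the highest other.

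Among 11146 probe sets without a gene symbol, which the comparisons did not use, 780 passed the threshold for vismodegib in Lgr5-positive cells and 81 in Lgr5-negative cells. For the population difference 987 passed in untreated mice and 12 after vismodegib, and 8 passed for the difference of effects. Over both populations 384 passed for vismodegib, and over both treatments 792 for the population.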

How the results depend on the processing

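Only the alternative with crossed mouse numbers was chosen after the data were seen. With a fold of at least 2 as a further condition, the counts were 739 for vismodegib in Lgr5-positive cells, 262 in Lgr5-negative cells, 960 for untreated populations, 397 for vismodegib over both populations and 402 for populations over both treatments, by construction fewer. On only the 4 arrays compared, 234 genes passed for vismodegib in Lgr5-negative cells and 11 for populations after vismodegib, where fewer samples leave fewer degrees of freedom. The latter count was 36 with no filter on dim genes and 105 with the mouse as a block, and vismodegib over both populations gave 1568 with a random mouse block in the 4-group model. The cause of these 3 shifts was not tested. The other planned settings that kept all arrays left each gene count within 1.5 times its value. The balance of directions depended on the normalisation. For vismodegib over both populations, 455 of 936 genes were higher after cyclic loess, against 512 of 974 in the main fit. In Lgr5-positive cells 792 of 1525 were higher after cyclic loess, against 917 of 1566.

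Leaving out each array in turn, with a lone array assumed to vary like the others, gave between 543 and 1823 genes for vismodegib in Lgr5-positive cells, the lowest without vismodegib Lgr5-positive array 1 (768 without its array 2, 1037 without untreated Lgr5-positive array 2). For Lgr5-negative cells it gave 65 to 523, with 65 and 137 without untreated Lgr5-negative arrays 2 and 1, 257 without vismodegib Lgr5-negative array 2 and 272 without either vismodegib Lgr5-positive array. Untreated populations gave 582 to 2852, with 582 and 1034 without untreated Lgr5-negative arrays 2 and 1. Populations after vismodegib gave 18 to 107, at the ends without vismodegib Lgr5-negative arrays 1 and 2, with 20 without either untreated Lgr5-negative array and 30 and 29 without vismodegib Lgr5-positive arrays 1 and 2. The difference of effects gave 2 to 251, with 2 and 79 without vismodegib Lgr5-positive arrays 1 and 2, 66 and 8 without untreated Lgr5-negative arrays 1 and 2 and 109 without vismodegib Lgr5-negative array 2. Without each mouse, vismodegib over both populations gave 330 to 733, with 415 and 330 without untreated mice 1 and 2. Populations over both treatments gave 742 to 2709, with 1005 and 742 without untreated Lgr5-negative arrays 1 and 2, 1113 and 865 without vismodegib Lgr5-positive arrays 1 and 2 and 1221 without vismodegib Lgr5-negative array 1.

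Every one of the 108 list calls was lost with an estimated correlation, which left 0 in each of the 7 contrasts. The test fry called 2 lists in place of 13 for populations after vismodegib, 7 in place of 15 for the difference of effects and 9 in place of 15 for vismodegib over both populations. Over left-out arrays the list counts were 13 to 17 and 12 to 17 for vismodegib in Lgr5-positive and Lgr5-negative cells, 17 to 19 and 11 to 16 for populations untreated and after vismodegib, 9 to 17 for the difference of effects (9 without vismodegib Lgr5-negative array 2), 15 to 16 for vismodegib over both populations and 15 to 19 for populations over both treatments. The Wnt/beta-catenin target list, called upward after vismodegib with a median of 0.04, had medians from −0.015 to 0.23 over left-out arrays, with −0.0073 and −0.015 without vismodegib Lgr5-negative array 1 and without vismodegib Lgr5-positive array 2. With the block 0 of the 108 calls were lost, and 8 lists not called before passed, among them the EGFR and ERK list for the difference of effects (adjusted p 0.0724, 0.0463 with the block).

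Of 199 gene results, 119 kept their direction and side of the threshold under the block, cyclic loess, the mean of probe sets and every left-out array, and 76 lost a call under at least 1 of these. Blocks ended 6 calls, cyclic loess 1 and the mean of probe sets 3. In deviations from group means, arrays of the same number across treatments had correlations across genes of 0.00964 in Lgr5-positive and −0.107 in Lgr5-negative cells, and mouse means −0.106. As a block the number gave 357 genes for Lgr5-negative cells and 679 for vismodegib over both populations, and crossed numbers gave 576 and 1022. Signals near the array minimum of 3.09 to 3.17 limit folds from dim genes such as Lyz2 in untreated Lgr5-positive cells.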

Other observations

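The values here rest on no test chosen after the result was seen. In Lgr5-positive cells, the Notch list had 3 higher and 2 lower of 16 (4 and 3 adjusted over the list alone) and was not called. The receptor Notch3 (1.39 ± 0.19), the ligand Dll1 (1.16 ± 0.23) and the regulator Dtx4 (2.03 ± 0.17) rose after vismodegib. In Lgr5-negative cells Notch3 (1.08 ± 0.19) and Dtx4 (0.91 ± 0.17) rose (Dtx4 with an adjusted p = 0.0584 with the mouse number as a block), 2 of 16 (2 and 0 adjusted over the list alone), and the list had an adjusted p = 0.274 with an estimated correlation. In untreated mice Notch3 (−1.35 ± 0.19) and Dtx4 (−1.20 ± 0.17) were lower and the glycosyltransferase Lfng (1.21 ± 0.31) higher in Lgr5-positive cells.

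Among TGF-beta and BMP genes, 3 rose and 6 fell of 22 in Lgr5-positive cells after vismodegib (4 and 8 adjusted over the list alone). The ligand Tgfb3 (−2.89 ± 0.21) and the BMP antagonist Grem1 (−1.89 ± 0.29) fell and the activin antagonist follistatin (Fst, 1.97 ± 0.18) rose. Tgfb3 fell in Lgr5-negative cells as well (−1.46 ± 0.21). Wnt ligands and receptors had 3 higher and 4 lower of 25 (3 and 7 adjusted over the list alone), with Wnt10a at 1.72 ± 0.22, the receptor Fzd2 at −1.71 ± 0.28 and Porcn, which acylates Wnt proteins, at −1.58 ± 0.27. Wnt5a fell in Lgr5-negative cells (−1.86 ± 0.22). Vimentin (Vim, 3.26 ± 0.22) and fibronectin (Fn1, 2.37 ± 0.38) rose and the laminin chain Lamb1 (−2.24 ± 0.18) fell in Lgr5-positive cells, in a matrix list with 4 higher and 4 lower of 16 (5 and 5 adjusted over the list alone). Macrophages also express vimentin and fibronectin, and their markers rose in the same comparison, 17 of 22 at a median of 2.29 (18 and 1 adjusted over the list alone), with an adjusted p = 0.221 with an estimated correlation. In Lgr5-negative cells 4 of that list fell and 0 rose (2 and 7 adjusted over the list alone), among them Col4a1 (−1.76 ± 0.21) and Sparc (−1.61 ± 0.24), with an adjusted p = 0.252 with an estimated correlation.

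Glycolysis and hypoxia genes had 6 higher and 1 lower of 20 in Lgr5-positive cells (9 and 2 adjusted over the list alone), with Egln3 (2.62 ± 0.61) and the angiogenic factor Vegfa (1.83 ± 0.19) higher and Ddit4 (−1.92 ± 0.26) lower, at an adjusted p = 0.678 with an estimated correlation. The transcription factor Mitf rose in Lgr5-positive cells after vismodegib (2.14 ± 0.23, or 1.14 as the mean of its probe sets). It was 1 of 2 risers among 15 melanocyte and Merkel cell markers (2 and 0 adjusted over the list alone). That list had a median of −0.11 and was not called. Macrophage markers rose in the same comparison, so the rise of Mitf cannot be assigned to melanocytes.

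Of the 54 genes named in the text and called for vismodegib in Lgr5-positive cells, 11 lost their call without vismodegib Lgr5-positive array 1, where 543 of all genes passed in place of 1566, and they include Dll1, Grem1, Egln3 and Porcn. Without array 2 of that group Dll1, Egln3 and Porcn lost it, and without either untreated Lgr5-negative array Egln3. In Lgr5-negative cells Notch3, Dtx4, Sparc, Tgfb3 and Wnt5a did not pass without untreated Lgr5-negative array 2, nor did the first 4 of these without array 1 of that group or vismodegib Lgr5-negative array 1. Notch3 and Dtx4 also did not pass without vismodegib Lgr5-negative array 2 or either vismodegib Lgr5-positive array. In untreated mice Lfng did not pass without either untreated Lgr5-negative array or untreated Lgr5-positive array 2.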
